A study of Mus musculus with 20 samples.

How the data were processed

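RNA was measured in isolated islets of 20 mice by poly(A)-selected RNA sequencing. Per the labels, 12 libraries came from a whole-body Cpeb1 line and 8 from a line in which Ins1-Cre, a recombinase made in beta cells, was present in knockout and control mice alike. The whole-body libraries formed 4 groups of 3 (knockout or control, female or male) in batch 1. The beta-cell libraries formed 4 groups of 2 in batch 2. Line and batch coincide, so levels were never compared across lines, only the knockout or sex effects measured within each line.

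Per the submitters' processing notes, reads were aligned to the mouse build mm10 with STAR 2.5.3a and summed per gene with RSEM 1.3.0. The deposited values were RSEM expected counts, held as whole numbers and not scaled for library size; rounding them changed nothing. The gene annotation, the strand setting and the use of molecular identifiers were not stated. The whole-body tables listed 55416 genes, including genes at 0. The beta-cell tables listed 16612 genes in females and 16767 in males, lacked genes with low counts by a rule that was not stated, and were therefore joined on the genes present in both. Symbols and positions came from a GRCm38 annotation, the same assembly as mm10, which held 94.0% of the gene identifiers of the whole-body tables and 99.8% of those of the beta-cell tables. Unmatched identifiers stayed in the tests without a position.

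Total counts per library lay between 41756830 and 112320368 in the whole-body line and between 40124922 and 101458838 in the beta-cell line. In control female 1 of the whole-body line Rn18s, a ribosomal RNA gene, took 60.5% of the counts, and its TMM scaling factor was 0.363. No library was left out, and no pair of replicates was a copy of another: the chi-square per degree of freedom between replicates was at least 85.5.

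Counts were scaled by TMM, filtered with filterByExpr and fitted with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3. The 12 whole-body libraries (18359 genes), the 8 beta-cell libraries (16284 genes) and all 20 (16284 genes) were fitted with 1 mean per group. There were 11 comparisons: knockout against control in females, in males and as the mean of both sexes, the male minus the female knockout effect, and males against females, each in both lines, and the difference of the mean knockout effect between lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 0.369 in the whole-body line and 0.258 in the beta-cell line. Levels are given as TMM-scaled CPM with the SD between animals. A fold against a group at 0 is a lower bound, computed against a floor of 3 counts per library. Intervals are at 95% confidence, and counting intervals and floors cover counting error only. Per the labels the libraries of a group came from separate animals.

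A set of 22 gene lists was tested with camera of limma 3.58.1, with the preset inter-gene correlation of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation; fry stood beside both. The lists covered acinar, alpha, delta and PP, duct, endothelial, immune, and stellate, mesenchymal and Schwann cells, beta cell identity, beta cell dedifferentiation, disallowed genes, insulin secretion, cell cycle, immediate early and isolation stress, unfolded protein response, oxidative phosphorylation, sterol synthesis, interferon and antigen presentation, prolactin response, cytoplasmic polyadenylation factors, reported CPEB1 target mRNAs, sex-linked genes and Cpeb1 neighbours. Members called over all genes and members called when adjusted over the list alone were counted. Genes within 5 Mb of Cpeb1 were compared with the other genes by Fisher's exact test on the share at an unadjusted p under 0.05. The overlap of such genes between lines was tested the same way. Mean list scores were compared by exact permutation within sex or genotype.

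The comparisons, lists and alternatives were fixed before the data were examined, and so was the rule for the genes to be named: Cpeb1; a panel of 23 islet and CPEB genes (among them Ins1, Ins2, Gcg, Sst, Ppy, Iapp, Pdx1, Mafa, Nkx6-1, Nkx2-2, Neurod1, Pax6, Ucn3, Slc2a2, G6pc2, Glp1r, Abcc8, Kcnj11, Aldh1a3, Cpeb2, Cpeb3 and Cpeb4); up to 10 called genes per direction with the largest change, a mean of at least 1 CPM and no overlap between groups within a sex; up to 4 members with the smallest p of each list with called members or a list call; and, where fewer than 5 genes passed, the 5 with the smallest p per direction. Up to 5 per direction were named for differences between effects, and counts of 5 or fewer were named in full. A few genes under this rule are not reported here.

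In the beta-cell line same-numbered knockout and control mice were of the same age, and their deviations from the group means correlated at 0.22 in females and 0.39 in males across genes, so the numbers were taken to pair the animals. With 2 animals per group these are 2 independent values. The whole-body numbers did not pair the animals.

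Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2 size factors within edgeR, no filter and a stricter filter (1 CPM), an adjusted p of 0.1, the replicate number as a block, age or an acinar score as a covariate, only the groups compared, control libraries only for sex, and each library left out in turn. Removal of Rn18s and Lars2 from the counts, wider and narrower windows around Cpeb1 and an overlap without chromosome 7 were chosen after seeing the data. The steps were tested on simulated counts drawn from the real means and library sizes, with 1 common spread for all genes and no pairs. In the mean of both sexes edgeR recovered 27% of genes changed 2-fold and 100% of those changed 4-fold in the whole-body line (18282 genes). It recovered 64% and 100% in the beta-cell line (16281 genes). Unchanged genes called in the whole-body and beta-cell line were 9 and 7 with edgeR, 11 and 9 with limma-voom, and 28 and 27 with DESeq2. Recovery in the real data, where the spread differs between genes, can differ from these values.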

Results

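RNA of isolated islets was sequenced from 20 mice of 2 lines in which Cpeb1 was disrupted. CPEB1 is an RNA-binding protein that controls the poly(A) tail length and the translation of mRNAs with a cytoplasmic polyadenylation element. The whole-body line had 3 knockout females, 3 control females, 3 knockout males and 3 control males. The line with Ins1-Cre, in which deletion is directed to beta cells, had 2 mice in each of the same 4 groups. Total counts in the whole-body line were 97105346, 94881216 and 92966950 in knockout females 1 to 3 and 41756830, 92170373 and 94375671 in control females 1 to 3. Knockout males 1 to 3 had 103291831, 85900719 and 88544818 counts and control males 97199554, 109089071 and 112320368. The beta-cell line had 40124922 and 83534374 counts in knockout females, 65287377 and 53972938 in control females, 69581742 and 79908314 in knockout males, and 67426235 and 101458838 in control males. Control female 1 of the whole-body line stood apart: Rn18s took 60.5% and Lars2 10.3% of its counts, the insulin genes Ins1 and Ins2 took 5.32%, and 19533 genes were above 0. In the other whole-body libraries Rn18s took between 0.962% and 7.49%. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were at 0 in every whole-body female library and had means of 29.8 ± 4.01, 24.98 ± 6.72 and 10.5 ± 1.70 CPM in males (SD, n = 6). Among beta-cell line males, knockout male 1 stood apart: Ddx3y had 12.1 CPM there against 35.0 to 36.7 CPM in the other 3 males, Uty 6.57 against 17.6 to 24.1, Kdm5d 5.44 against 12.9 to 23.8 and Eif2s3y 9.7 against 24.2 to 25.6 CPM. The chi-square per degree of freedom between the knockout males was 707, against 85.5 to 140 between the libraries of the other beta-cell groups. This library was kept, and the cause was not tested.

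Cpeb1 mRNA was lower in knockout than in control islets in both lines and both sexes, and the knockout and control libraries did not overlap. Cpeb1 (ENSMUSG00000025586) is a protein-coding gene on the minus strand of chromosome 7, positions 81347026 to 81455465 in GRCm38. In whole-body females it had 34.4, 26.0 and 24.99 CPM in knockout mice 1 to 3 and 63.4, 60.7 and 38.3 CPM in controls. In whole-body males the knockout values were 28.2, 38.0 and 28.3 CPM and the control values 59.3, 55.7 and 65.3 CPM. Beta-cell knockout females had 27.7 and 27.8 CPM against 50.8 and 62.3 CPM in controls, and knockout males had 30.3 and 28.7 CPM against 57.7 and 69.2 CPM. The values are sums over the whole gene, so they do not show which exons the remaining reads covered.

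The log2 fold change of Cpeb1 was -0.93 (SE 0.204) in whole-body females and -0.93 (SE 0.203) in whole-body males, with means over both sexes of 30.0 ± 5.13 CPM in knockout and 57.1 ± 9.78 CPM in control mice (SD, n = 6 each). These changes did not pass in edgeR (adjusted p = 0.444 in females, 0.523 in males and 0.128 for the mean of both sexes). DESeq2 called all 3 (adjusted p = 0.00694, 0.00209 and 1.04e-06) and limma-voom called the mean of both sexes (0.0284). Without control female 3, the control with the least Cpeb1, edgeR called it in females (log2 -1.06, adjusted p = 0.0454) and for the mean (-1.01, 0.00882). Beta-cell knockout islets had changes of -1.02 (SE 0.135, adjusted p = 0.194) in females and -1.10 (SE 0.135, 0.2) in males, and for the mean of both sexes Cpeb1 fell by 1.06 on the log2 scale (SE 0.0956, edgeR adjusted p = 0.0224), from 60.0 ± 7.73 to 28.6 ± 1.18 CPM (SD, n = 4 each). That call was lost when any 1 of the 8 libraries was left out, with log2 changes from -1.14 without control female 1 (adjusted p = 0.059) to -0.99 without control female 2 (0.0698); with the pairs as a block it was kept (adjusted p = 0.018). The effect did not differ detectably between sexes (male minus female -0.01 and -0.08) or between lines (0.13, SE 0.198).

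**Figure D1:**
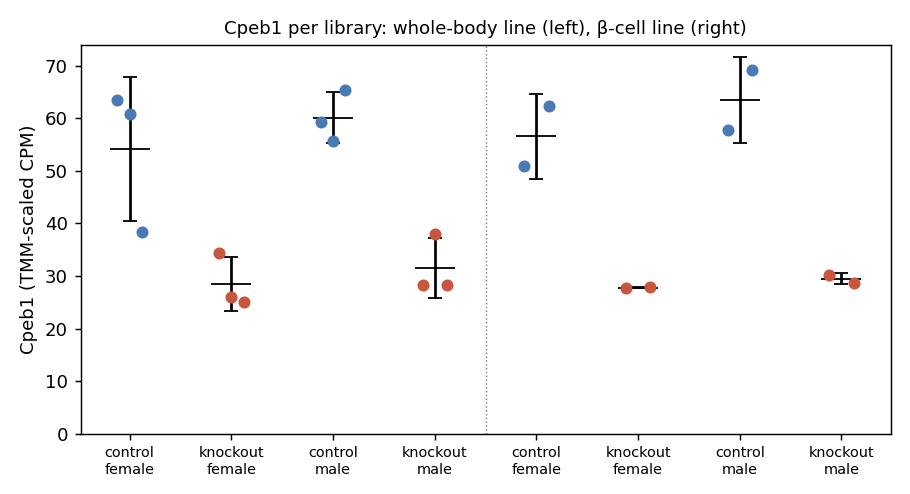
Cpeb1 in every library as TMM-scaled CPM, controls in blue and knockouts in red, whole-body line left and beta-cell line right of the dotted line; points are libraries, horizontal lines means and bars SD. Knockout libraries lie between 24.99 and 38.0 CPM and controls between 38.3 and 69.2 CPM.

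Whole-body knockout females were compared with control females to ask what loss of Cpeb1 in all tissues changes in female islets. Of 18359 genes, 1 rose and 0 fell. The lincRNA 2900076A07Rik (chromosome 7, 81523550 to 81531498, beyond the start of Cpeb1) rose by 1.42 on the log2 scale (SE 0.132, adjusted p = 0.00683), from 1.93 ± 0.0292 to 5.18 ± 0.135 CPM (SD, n = 3). Among genes that did not pass, Tcf24 had 0.79 and Sh3gl3, an endophilin gene near Cpeb1, 4.12 (adjusted p = 0.214 each), Gm34225 1.18 and Ptp4a2 0.42. The protocadherins Pcdhgc3 and Pcdhga5 had -0.74 and -0.84, Eme2 -0.62, Spock2 -0.56 and Cdon -0.59 (adjusted p = 0.444). The hormones lay near their control levels, with 0.01 for Ins1, 0.09 for Ins2, 0.11 for Iapp, 0.18 for Gcg, -0.01 for Sst and 0.14 for Ppy. Glp1r, the GLP-1 receptor, had -0.78 (449.2 ± 107.3 against 774.1 ± 227.8 CPM), Abcc8, a subunit of the ATP-sensitive potassium channel, -0.44, and Cpeb3 -0.80 (edgeR adjusted p = 0.444 each). The other panel genes lay between -0.40 for Cpeb4 and 0.20 for Aldh1a3.

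Acinar enzymes ranked lowest of the cell type lists in these females (33 genes, median log2 -2.34; camera adjusted p = 1.36e-08, adjusted p = 0.739 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. Endothelial (median 0.47, adjusted p = 3e-05), immune (0.52, 0.000233) and stellate, mesenchymal and Schwann cell genes (0.41, 0.00336), disallowed (0.42, 0.00167), interferon (0.34, 0.00167) and oxidative phosphorylation genes (0.14, 0.00336) ranked higher in camera, and insulin secretion (-0.11, 0.0199) and identity genes (-0.11, 0.0312) lower. All of these had an adjusted p of 0.739 with an estimated correlation. Without control female 1, the library rich in ribosomal RNA, oxidative phosphorylation genes turned direction (camera adjusted p = 0.0828), and without control female 2 stellate, mesenchymal and Schwann cell genes did (0.723). The prolactin response list (16 genes, median -0.30, adjusted p = 0.000809) ranked lower as well (adjusted p = 0.663 with an estimated correlation). It had 2 lower members when adjusted over the list alone and 0 over all genes; Ehhadh, an enzyme of peroxisomal fatty acid oxidation, had -1.07, Tph2, a serotonin-synthesis enzyme, -0.92, and Igf1r, the IGF-1 receptor, -0.91. In edgeR 2049 genes had an unadjusted p under 0.05; DESeq2 called 121 and limma-voom 0. The edgeR count was 0 without knockout female 2, knockout female 3 or control female 2, which left 2900076A07Rik at log2 1.43, 1.47 and 1.44 (adjusted p = 0.0687, 0.0564 and 0.0784). It was 2 without knockout female 1 and 32 (7 up, 25 down) without control female 3.

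In whole-body knockout males 4 genes rose and 0 fell, all 4 on chromosome 7. Aldh1a3 (66390890 to 66427517, minus strand), which makes retinoic acid from retinal and is used as a marker of dedifferentiated beta cells, rose by 2.66 (SE 0.235, adjusted p = 0.00206), from 2.47 ± 0.217 CPM to 15.7 ± 4.54 CPM (SD, n = 3), with 20.4, 11.4 and 15.1 CPM in knockout males 1 to 3. The lincRNA 2900076A07Rik rose by 1.49 (SE 0.13, 0.00206; 2.83 ± 0.315 to 7.97 ± 0.438 CPM) and the lincRNA Gm34225 (115031937 to 115066824) by 2.04 (SE 0.215, 0.00849; 1.88 ± 0.229 to 7.70 ± 1.70 CPM). Me3 (89632392 to 89854359), a mitochondrial malic enzyme, rose by 1.2 (SE 0.141, 0.0176; 3.60 ± 0.127 to 8.29 ± 0.938 CPM). Among genes that did not pass, Frmd5 had 0.84 (adjusted p = 0.135). The B-cell genes Blk (-4.75, 0.125) and Cd37, Fcmr and Ighd (-3.42, -3.41 and -4.19, 0.394) and Tfrc, the transferrin receptor (-0.68, 0.465), had the smallest p among lower genes. In the panel G6pc2 had 0.54 (adjusted p = 0.619), Glp1r -0.44 (0.722), Slc2a2 -0.40 (0.594) and Ppy -0.52, and the others lay between -0.23 for Neurod1 and 0.30 for Pdx1.

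Acinar genes were again the lowest list in males (median -3.32; camera adjusted p = 3.38e-26, adjusted p = 0.508 with an estimated correlation): 0 of 33 members were called over all genes and 25 lower when adjusted over the list alone. Amy2a5, a pancreatic amylase, had 81.3 ± 23.5 CPM in knockout and 709.8 ± 302 CPM in control males (log2 -3.13), and Try5, Gp2 and Pnliprp2 had -3.62, -3.55 and -3.68 (edgeR adjusted p = 0.594). Beside this shift in acinar RNA, the dedifferentiation list ranked higher (17 genes, median 0.49; camera adjusted p = 0.00028, adjusted p = 0.145 with an estimated correlation; fry 0.0241). Of its members Aldh1a3 was called over all genes and 2 were higher when adjusted over the list alone; Serpina7 had 1.33, and the gut hormone genes Cck and Gast had 4.09 and 0.91. Immune genes ranked lower (median -0.37, adjusted p = 1.1e-08; 0.728 with an estimated correlation), with 4 lower members when adjusted over the list alone; the macrophage gene Lyz2 had -1.47 and the B-cell receptor genes Cd79a and Cd79b -1.42 and -3.09. Stellate, mesenchymal and Schwann cell (median -0.56, adjusted p = 0.00202), sterol synthesis (-0.13, 0.0076), interferon (-0.15, 0.0123) and delta and PP genes (-0.17, 0.0274) ranked lower and oxidative phosphorylation genes (0.09, 0.0274) higher in camera, with an adjusted p between 0.728 and 0.891 with an estimated correlation. Oxidative phosphorylation genes turned direction with the acinar score as a covariate (camera adjusted p = 0.0687).

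In edgeR 1371 genes had an unadjusted p under 0.05 in males; DESeq2 called 293 and limma-voom 7. Aldh1a3 and 2900076A07Rik were called in each of the 12 fits without 1 library. The count was 2 without knockout male 3 or without control male 1, 2 or 3, where Gm34225 had log2 changes of 1.82, 2.03, 2.11 and 1.93 (adjusted p = 0.0501, 0.115, 0.0804 and 0.17) and Me3 1.15, 1.23, 1.17 and 1.18 (0.153, 0.163, 0.217 and 0.172). Me3 was also lost without knockout male 2 (1.14, 0.0861) or knockout female 1, 2 or 3 or control female 2 (1.18 in each; 0.0682, 0.0742, 0.0867 and 0.0711).

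Over both sexes (n = 6 against 6), 6 genes rose in whole-body knockout islets and 0 fell, 5 of them on chromosome 7. These were 2900076A07Rik (log2 1.46, SE 0.0928, adjusted p = 0.000143), Gm34225 (1.61, 0.152, 0.00411), Me3 (0.93, 0.0998, 0.00952) and Aldh1a3 (1.43, 0.161, 0.0112). The other 2 were Sh3gl3 (82173840 to 82307419; 3.04, 0.409, 0.0417) and Tcf24, a transcription factor gene on chromosome 1 (9960163 to 9967932; 0.62, 0.0806, 0.0348; 51.5 against 34.8 CPM). Sh3gl3 had 1.47 ± 0.538 CPM in knockout and 0.171 ± 0.131 CPM in control islets. Beta cell genes did not pass. Ins1 had 0.07 and Ins2 0.10, Iapp 0.15, Ucn3 -0.03 and Slc2a2 -0.22. Of the transcription factors Pdx1 had 0.03, Mafa -0.07, Nkx6-1 0.03, Nkx2-2 -0.13, Neurod1 -0.25 and Pax6 0.03. G6pc2 had 0.34, Glp1r -0.61 (adjusted p = 0.524), Abcc8 -0.22 and Kcnj11 0.01. Gcg had 0.05, Sst -0.11, Ppy -0.19, and the related Cpeb2, Cpeb3 and Cpeb4 had -0.10, -0.48 and -0.25.

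Acinar genes had a median of -2.81 over both sexes (camera adjusted p = 7.78e-31, adjusted p = 0.37 with an estimated correlation), 29 of 33 were lower when adjusted over the list alone and 0 over all genes. The mean acinar score differed by -2.38 log2 units between knockout and control islets (exact permutation within sex, p = 0.02, adjusted p = 0.33 over the lists). The dedifferentiation genes had a median of 0.20 (camera adjusted p = 0.000576, adjusted p = 0.197 with an estimated correlation; fry 0.0242), 1 called member, 3 higher when adjusted over the list alone and an exact permutation p of 0.03 (adjusted p = 0.33). Endothelial (median 0.26, adjusted p = 5.01e-05), oxidative phosphorylation (0.11, 7.58e-05) and unfolded protein response genes (0.11, 0.0442) ranked higher in camera, with adjusted p = 0.874, 0.931 and 0.931 with an estimated correlation. Sterol synthesis (-0.09, adjusted p = 0.00154), prolactin response (-0.17, 0.00776) and identity genes (-0.08, 0.0442) ranked lower, with adjusted p between 0.507 and 0.931 with an estimated correlation. The sex-linked list was called as well (camera adjusted p = 0.00398, adjusted p = 0.636 with an estimated correlation), but 4 of its 9 members are Y-linked genes, so that this call rests in part on female libraries without the gene and is not read as a change. With the acinar score as a covariate the endothelial (camera adjusted p = 0.000382), oxidative phosphorylation (0.322), identity (0.314) and prolactin response lists (0.918) turned direction. The reported CPEB1 target mRNAs (21 genes) had a median of -0.02 and were not called (camera adjusted p = 0.857). In edgeR 1083 genes had an unadjusted p under 0.05, DESeq2 called 197 and limma-voom 10. The edgeR count was 2, 2900076A07Rik and Gm34225, without knockout female 2 or 3, control female 2, knockout male 3 or control male 1, 2 or 3, and 11 without control female 3. Aldh1a3 then had log2 changes from 1.40 (adjusted p = 0.0773, without control male 1) to 1.47 (0.0816, without control male 3), and Me3 from 0.90 (0.0601, without knockout male 3) to 0.95 (0.0584, without control male 1). Sh3gl3 was lost without any 1 library but control female 1 and Tcf24 without any but knockout female 1 and control female 3. Across the fits that lost them, Sh3gl3 ran from 2.88 without control male 1 to 3.46 without control female 2, and Tcf24 from 0.58 without knockout female 2 to 0.64 without control female 2.

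**Figure D2:**
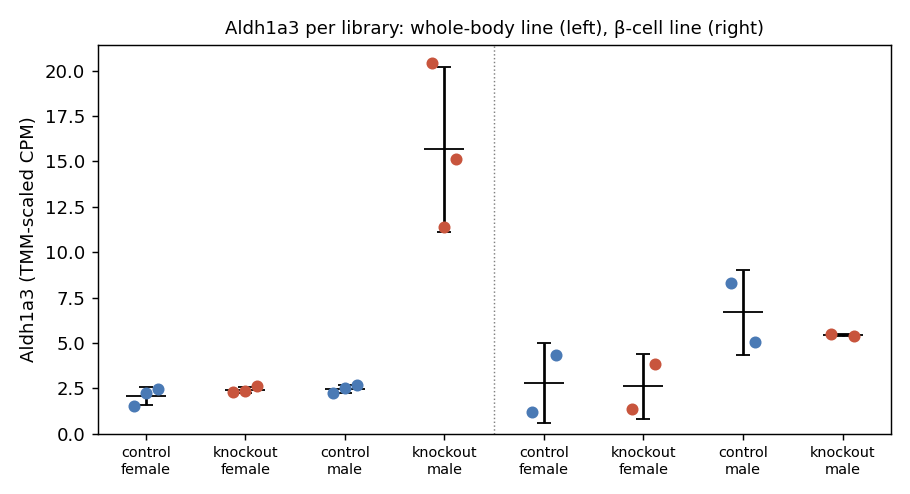
Aldh1a3 in every library as TMM-scaled CPM, controls in blue and knockouts in red, whole-body line left and beta-cell line right of the dotted line; points are libraries, horizontal lines means and bars SD. The 3 whole-body knockout males lie between 11.4 and 20.4 CPM, against a mean of 2.47 CPM in control males.

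The difference between the knockout effects of males and females was tested in the same libraries. No gene passed over all 18359 (edgeR 0 called, 2000 at an unadjusted p under 0.05; DESeq2 472, limma-voom 0). Genes with the smallest p were, where the male effect was higher, Aldh1a3 (2.46, 95% interval 1.76 to 3.17, adjusted p = 0.12), Gata4 (4.61), Slc6a8 (1.03), Frmd5 (0.87) and Mov10 (0.79; adjusted p = 0.299 each). Where the female effect was higher they were the B-cell genes Blk (-6.63, adjusted p = 0.12), Fcmr (-5.68), Ighd (-6.59) and Cd37 (-5.10) and the desmosomal gene Dsc3 (-8.22; 0.299). Adjusted among the 6 genes called over both sexes alone, Aldh1a3 (edgeR, adjusted p = 5.95e-05), Me3 (0.54, 0.0298), Gm34225 (0.86, 0.0298) and Sh3gl3 (-2.15, 0.0298) passed, and 2900076A07Rik (0.07, 0.725) and Tcf24 (-0.33, 0.0738) did not. These 6 genes were chosen by calls in the same libraries, with the same estimates of spread. Their adjusted p is therefore no independent support. Without knockout male 2 edgeR called 3 genes, among them Aldh1a3 (2.64, adjusted p = 0.0335) and Gata4 (5.09, 0.0335).

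Genes close to Cpeb1 were counted because a targeted allele can carry neighbouring DNA of another strain. Of 81 genes within 5 Mb of Cpeb1, 23 (28.4%) had an unadjusted p under 0.05 in the whole-body line over both sexes, against 5.79% of the other genes (odds ratio 6.45, 95% interval 3.78 to 10.7; Fisher's exact test, p = 1.48e-10). For the beta-cell line the count was 13 of 74 (17.6%) against 3.58% (5.74, 2.88 to 10.6; Fisher's exact test, p = 2.36e-06). Between 5 and 25 Mb the odds ratio against other chromosomes was 1.85 (1.15 to 2.84) in the whole-body line and 5.12 (3.34 to 7.63) in the beta-cell line, and farther along chromosome 7 it was 1.21 (0.935 to 1.55) and 1.57 (1.14 to 2.13). Within the whole-body line females had 22 of 81 such genes (odds ratio 2.99) and males 13 of 81 (2.38). Of the fixed neighbour list 5 of 24 genes passed in the whole-body line (4.22, Fisher's exact p = 0.0117) and 2 of 20 in the beta-cell line (2.95, p = 0.164). The 5 Mb odds ratio was 2.38 without control female 3 of the whole-body line and 2.84 without control female 2 of the beta-cell line.

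**Figure D3:**
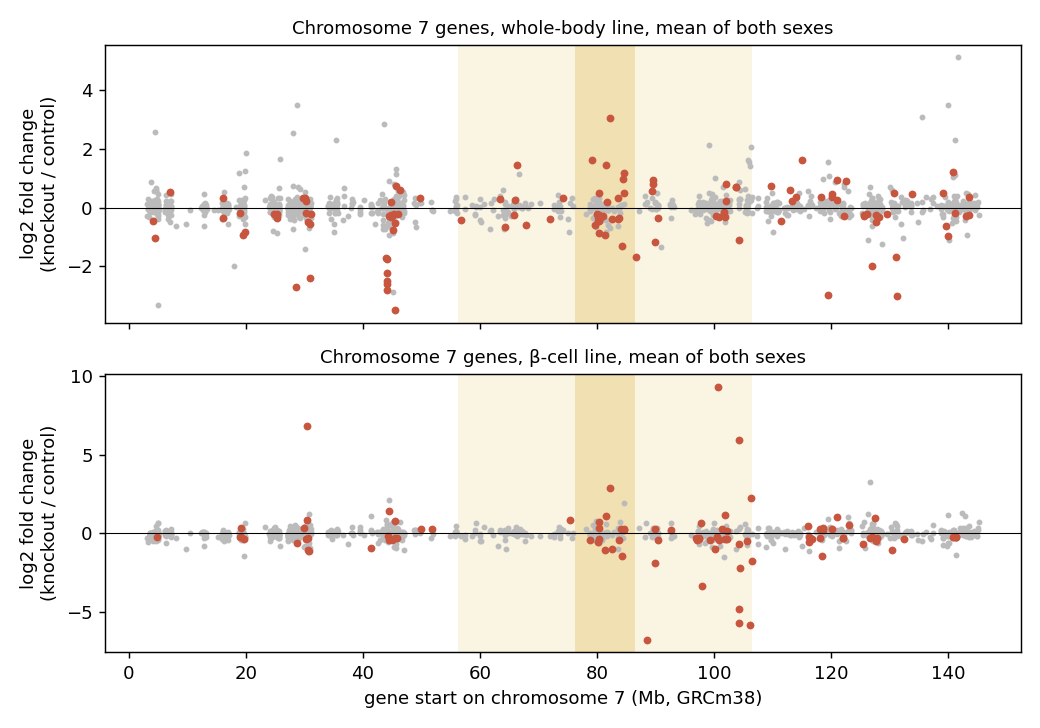
Knockout log2 fold change (mean of both sexes) of chromosome 7 genes by gene start (Mb, GRCm38) in the whole-body and the beta-cell line; red points have an unadjusted p under 0.05, grey points do not, and shading marks genes within 5 Mb (dark) and 5 to 25 Mb (light) of Cpeb1. Of the genes within 5 Mb, 23 of 81 and 13 of 74 are red; fitted values of genes at 0 in a group depend on the prior count.

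Beta-cell knockout females were compared with Ins1-Cre control females to ask what loss of Cpeb1 in beta cells changes. Of 16284 genes, 1 rose and 1 fell. Capza1-ps1, an actin-capping pseudogene on chromosome 1, rose by 3.58 (SE 0.255, adjusted p = 0.0164), from 0.446 ± 0.0253 to 5.35 ± 0.925 CPM (SD, n = 2). Trim12a, a TRIM gene on chromosome 7, was at 0 in both knockout libraries and at 2.69 ± 0.911 CPM in controls, at least 50.5-fold lower (edgeR adjusted p = 0.0492). Pseudogenes and genes with close paralogs share reads with their relatives, so these counts are less certain than those of unique genes. Higher values that did not pass were 4.50 for Mrpl48-ps (adjusted p = 0.152), at least 39.8-fold for Gm35082, 0.53 for Lpgat1 (0.438) and 1.01 for Akap13 (165.7 ± 3.45 against 82.1 ± 9.23 CPM, 0.496). Lower ones were at least 82.7-fold for the interferon-induced Gvin1 (0.0671), at least 20.7-fold for Rps13-ps2 and -1.37 for Arnt2 (0.176). Of these genes Gm35082, Akap13, Gvin1, Rps13-ps2 and Arnt2 lie on chromosome 7, as Cpeb1 does. Sst, the delta cell hormone, had 3789 ± 55.3 CPM against 6698 ± 491.2 CPM (-0.82, SE 0.116, adjusted p = 0.263) and Gcg -0.59. The other panel genes lay between -0.33 for Ppy and 0.51 for G6pc2.

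Delta and PP cell genes ranked lower in these females (12 genes, median -0.48; camera adjusted p = 4e-06, adjusted p = 0.385 with an estimated correlation), with 0 members called over all genes and 3 lower when adjusted over the list alone. Alpha cell genes ranked lower too (median -0.32, adjusted p = 0.00374; 0.385 with an estimated correlation). Endothelial (-0.49, adjusted p = 6.81e-05), interferon (-0.19, 0.0024), oxidative phosphorylation (-0.08, 0.00786) and immune genes (-0.47, 0.0152) ranked lower and identity (0.15, 0.00926) and acinar genes (0.79, 0.0182) higher in camera, none with an estimated correlation (adjusted p = 0.921). Immune genes turned direction without knockout female 2 (camera adjusted p = 0.937) or control female 1 (0.678). In edgeR 506 genes had an unadjusted p under 0.05; DESeq2 called 29 and limma-voom 2. With DESeq2 size factors edgeR called 1 gene up and 0 down (100% higher, against 50%), and with the pairs as a block it called 3. The count was 0 without knockout female 1 or 2, control female 1 or control male 1 or 2. Capza1-ps1, also lost without control female 2 (3.63, adjusted p = 0.158), ran from 3.39 (0.151, without knockout female 1) to 3.75 (0.111, without knockout female 2). Trim12a was lost without any 1 of the 8 libraries, with adjusted p from 0.061 without knockout male 1 to 0.567 without knockout female 2.

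In beta-cell knockout males 0 genes passed in edgeR, DESeq2 called 19 and limma-voom 0. An unadjusted p under 0.05 was found for 302 genes (1.85%), fewer than that threshold would give without any effect. The shares in the other knockout comparisons of this line were 3.11% in females, 3.65% over both sexes and 1.3% for males minus females. The fit did not use the pairs and may be conservative, so that 0 calls do not show that nothing changed. Among the smallest p were those of the antibody genes Igha (2.33, adjusted p = 0.211) and Jchain (2.80, 0.582), of 2900076A07Rik (1.06), S100a1 (0.55) and Gm35082 (at least 17.4-fold higher), and of Arnt2 (-1.49, adjusted p = 0.2), Dynlt1b (-0.67), Rps13-ps2 (-4.24) and Reep6 (-0.37). The T-cell gene Cd3d was at 0 in control males and at least 8.86-fold higher in knockout males. In the panel Sst had -0.29, Gcg -0.38, Ppy -0.40, Aldh1a3 -0.30 and Cpeb4 0.30, and the other panel genes reported here lay between -0.21 for Glp1r and 0.15 for Slc2a2. Acinar genes were called lower in camera (adjusted p = 0.000175; 0.84 with an estimated correlation) although their median was 0.30. Duct genes ranked lower (-0.14, adjusted p = 0.0377) and immune (0.33, 0.0166) and interferon genes (0.18, 0.0377) higher in camera, none with an estimated correlation (adjusted p = 0.84). The acinar list turned direction without knockout male 2 (camera adjusted p = 4.33e-22), and without knockout male 1 the immune (0.682) and interferon lists (0.0936) did. Without control female 1 or 2 edgeR called 3 genes, and 1 without control male 1. Without knockout male 1, the library low in Y-linked transcripts, it called 0.

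Over both sexes of the beta-cell line (n = 4 against 4) 3 genes rose and 3 fell. Of these 6 genes 4 lie on chromosome 7, Cpeb1 among them, against 1238 of the 16284 genes tested. Arnt2, a transcription factor gene that starts at position 84246278 of chromosome 7, fell by 1.43 (SE 0.122, adjusted p = 0.0207), from 31.5 ± 4.998 to 11.8 ± 1.83 CPM, beside Cpeb1 and Trim12a (fitted log2 -5.72, adjusted p = 0.0297). The pseudogenes Mrpl48-ps (4.64, SE 0.385, 0.0207, from 0.1005 ± 0.0732 to 2.47 ± 1.003 CPM) and Capza1-ps1 (1.96, SE 0.166, 0.0207) rose. So did Gm35082, which was at 0 in all control libraries. Capza1-ps1 had 5.68 ± 0.747 CPM in knockout and 2.59 ± 2.49 CPM in control islets, with controls from 0.428 to 4.99 CPM. Its change was 3.58 in females, and the male minus female difference was -3.24. Trim12a was at 0 in knockout females, with a fitted male minus female difference of 9.68. The means of Capza1-ps1 and Trim12a thus rest mostly on females. Hormones and beta cell genes did not pass. Ins1 had -0.12, Ins2 -0.10, Iapp 0.01, Gcg -0.48, Sst -0.56 (adjusted p = 0.224) and Ppy -0.36. G6pc2 had 0.30, Slc2a2 0.17, Glp1r -0.07, Abcc8 -0.03 and Kcnj11 0.03. Pdx1 had 0.04, Mafa 0.06, Nkx6-1 0.11, Nkx2-2 -0.06, Neurod1 0.03, Pax6 -0.03 and Ucn3 0.08. Aldh1a3 had -0.18 (95% interval -1.32 to 0.95), and Cpeb2, Cpeb3 and Cpeb4 had 0.07, -0.15 and 0.27.

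Delta and PP genes had a median of -0.24 (camera adjusted p = 0.000316, adjusted p = 0.45 with an estimated correlation), with 0 members called over all genes and 3 lower when adjusted over the list alone. Alpha (-0.19, adjusted p = 0.00743; 0.45 with an estimated correlation), endothelial (-0.31, 0.00051), oxidative phosphorylation (-0.05, 0.00743) and duct genes (-0.15, 0.0321) ranked lower as well, the last 3 with adjusted p = 0.978 with an estimated correlation. The reported CPEB1 targets had a median of 0.04. In edgeR 594 genes had an unadjusted p under 0.05; DESeq2 called 38 and limma-voom 6, and the block on pairs gave 8. The edgeR count was 0 without knockout female 1 or 2 or control male 2, 1 without knockout male 2 or control male 1, and 3 without control female 2. None of the 6 genes kept its call in all 8 fits without 1 library; Arnt2 ran from -1.31 (adjusted p = 0.0543, without control female 2) to -1.46 (0.165, without knockout female 1).

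Between the sexes of the beta-cell line the male and female knockout effects differed for no gene in edgeR (0 called, 212 at an unadjusted p under 0.05; DESeq2 7, limma-voom 0). Among the smallest p were those of Igha (4.07, adjusted p = 0.115) and Jchain (4.05, 0.479), of Trim12a (fitted 9.68, 0.179) and Gvin1 (fitted 10.84, 0.183), both at 0 in knockout females, and of Capza1-ps1 (-3.24, 0.115) and Pttg1 (-2.62). Igha, the IgA heavy chain, had means of 9.04 and 30.0 CPM in knockout and control females and 21.9 and 4.38 CPM in knockout and control males. Without knockout female 1 edgeR called Igha (4.58, adjusted p = 0.0185), and without control female 1 it called 1 gene.

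The mean knockout effect differed between lines for 3 of 16284 genes, all on chromosome 7: Trim12a (whole-body minus beta-cell, fitted 5.94, adjusted p = 0.00123), Rps13-ps2 (fitted 7.03, 0.00529) and Gm34225 (2.42, SE 0.364, 0.0382). Trim12a and Rps13-ps2 were at 0 in beta-cell knockout females, so that the size of their fitted differences depends on how the fit treats a count of 0. Mt3, a metallothionein gene, had 1.35 and the myosin gene Myo7a, also on chromosome 7, had 3.29 (edgeR adjusted p = 0.0995 each). Myo7a passed without knockout male 1 (2.86, adjusted p = 0.000416) or 2 (4.52, 2.86e-06) of the beta-cell line. Gm34225 was lost without any 1 library but control female 3 of the whole-body line and knockout female 2, control female 1 and control male 2 of the beta-cell line, with values from 2.165 (adjusted p = 0.0807) without knockout female 1 of the beta-cell line to 2.47 (0.0716) without knockout male 2 of the whole-body line. In edgeR 556 genes had an unadjusted p under 0.05; DESeq2 called 14 and limma-voom 7. Dedifferentiation genes ranked higher in the whole-body than in the beta-cell effect (median difference 0.37; camera adjusted p = 0.000119, adjusted p = 0.0412 with an estimated correlation; fry 0.0632).

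Knockout effects of the lines were compared across 16215 genes in separate animals. At an unadjusted p under 0.05 there were 1020 genes in the whole-body and 581 in the beta-cell line, and 68 in both, against 36.5 for independent lists (odds ratio 2.04, 95% interval 1.55 to 2.66; Fisher's exact test, p = 7.74e-07). Of the 68, 61 (89.7%) moved the same way, among them 2900076A07Rik (1.46 and 1.09), Sh3gl3 (3.04 and 2.91) and Arnt2 (-1.29 and -1.43). Others were Gdf11, a growth factor of the TGF-beta family (0.88 and 0.63), the interferon-induced Mx1 (1.82 and 1.23), S100a1 (0.63 and 0.51), Otoa (0.94 and 1.02), Spock2 (-0.39 and -0.34) and Trp53 (-0.32 and -0.22). Off chromosome 7, 50 genes were shared against 29.6 (1.81, 1.32 to 2.46), and 44 moved the same way. At an unadjusted p under 0.01 an excess off chromosome 7 was not detectable, with 2 genes shared against 1 (1.95, 0.23 to 7.41; Fisher's exact p = 0.28), while chromosome 7 had 9 against 1.4 (9.49, 3.69 to 22.5). Over all genes the log2 fold changes did not correlate (Pearson r -0.028, Spearman rho 0.011, across genes, which are not independent replicates). Without control female 3 of the whole-body line the odds ratio was 1.07.

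Males and females of the whole-body line were compared over both genotypes (n = 6 against 6), and 640 genes were higher and 397 lower in males, 125 of them at least 2-fold. Alpha cell genes were lower in males: of 17 members 7 fell and 1 rose, and 8 and 1 when adjusted over the list alone. Irx1 fell by 1.29 (edgeR adjusted p = 0.01), Irx2 by 0.95 (0.00857) and Slc38a5 by 0.75 (0.0117). Gcg, the glucagon gene, fell by 0.65 (0.0342) and Ttr by 0.60 (0.019). Gc, a vitamin D binding protein, rose by 0.59 (0.00927). The list ranked lower in males (median -0.48; camera adjusted p = 0.000218, adjusted p = 0.499 with an estimated correlation; fry 0.0192), and the alpha score was lower in males (male minus female -0.47, exact permutation within genotype, p = 0.005, the smallest possible). Acinar genes also ranked lower in males (median -1.82; camera adjusted p = 0.00016, adjusted p = 0.959 with an estimated correlation), with 0 members called over all genes.

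Genes of the unfolded protein response were higher in whole-body males: 18 of 26 rose, and 22 when adjusted over the list alone (median 0.63; camera adjusted p = 9.56e-18, adjusted p = 0.239 with an estimated correlation; fry 0.000387). Manf, a secreted stress-response factor, rose by 0.92 (339.8 ± 44.1 against 179.1 ± 18.0 CPM, adjusted p = 0.000811), Sdf2l1 by 1.03 (0.00254), the transcription factor Atf4 by 0.78 (0.00312) and the chaperone cofactor Dnajb11 by 0.70 (0.00421). Of the insulin secretion genes 6 rose and 1 fell over all genes, and 8 and 3 when adjusted over the list alone; Slc17a9 rose by 0.84 (0.00309), Scg2 by 0.71 (0.0123), Cpe by 0.42 (0.0123) and Scg3 by 0.33 (0.02). Of the identity genes 4 rose and 1 fell, and 5 and 1 when adjusted over the list alone, with Ins1 higher by 0.45 (0.0167), Iapp by 0.50 (0.0173) and G6pc2 by 0.65 (0.0364), and Npy lower (-1.16, 0.0325). Dedifferentiation genes went both ways: Aldh1a3 (1.46, adjusted p = 0.00158) and Bambi (0.73, 0.000944) rose and Fev (-1.19, 0.000998) and Neurog3 (-1.05, 0.00559) fell. Oxidative phosphorylation genes ranked higher (median 0.19, 2 called up, Cycs 0.63 and Atp5g1 0.45, and 0 when adjusted over the list alone; camera adjusted p = 1.51e-06, adjusted p = 0.959 with an estimated correlation).

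Among single genes other than Y-linked ones, C7 (3.48, adjusted p = 0.0341) and Rgs2, a regulator of G protein signalling (2.85, 0.00158; 226.7 ± 101.5 against 31.3 ± 6.21 CPM), were higher in males, with Hbb-bt (1.92), Alas2 (1.92), Meltf (1.86) and Dapl1 (1.78, 0.000588). Lower in males were Prom2 (-1.61), Lingo3 (-1.59), Insyn2a (-1.33), Vcan (-1.33), Col8a2 (-1.23) and Gper1, a G protein-coupled estrogen receptor (-1.14). The stress gene Dnajb1 rose by 0.95 (0.0315) and the neighbour gene Sec11a by 0.61. Sterol synthesis genes ranked higher (median 0.19, 2 called up, Insig1 0.52 and Idi1 0.38, and 7 when adjusted over the list alone; camera adjusted p = 0.00178, adjusted p = 0.663 with an estimated correlation). Delta and PP (median -0.39, adjusted p = 0.0145; 5 lower when adjusted over the list alone) and prolactin response genes (-0.09, 0.0145; Ivd among those called lower, 5 when adjusted over the list alone) ranked lower, with adjusted p = 0.499 with an estimated correlation. The sex-linked list of 9 genes had 4 higher and 3 lower members in males (camera adjusted p = 0.0261, adjusted p = 0.729 with an estimated correlation), with a median of -0.31 and a mean of 4.46 that rests on fitted values of Y-linked genes; Uty had 18.1 ± 1.70 against 0.0110 CPM.

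In edgeR 4248 genes had an unadjusted p under 0.05; DESeq2 called 2660 and limma-voom 1450, and the age-adjusted fit called 616. In control libraries alone (n = 3 against 3) 11 genes were called, all higher in males, and Aldh1a3 had a log2 difference of 0.22 there. The count was 308 without control male 1, 365 without knockout male 3, 406, 525 and 423 without knockout female 1, 2 or 3, 499 without knockout male 2, 423 and 581 without control male 2 or 3, and 1656 without control female 3. Of the genes named, C7, Insyn2a, Gper1, Npy, G6pc2, Dnajb1, Ins1, Iapp, Scg3, Cycs, Atp5g1, Ivd, Insig1 and Idi1 lost their call without at least 1 library. Without control male 1 C7 had 3.46 (adjusted p = 0.0822), Insyn2a -1.21 (0.0751), Gper1 -1.19 (0.0618) and G6pc2 0.66 (0.0851). The same fit gave Ins1 0.41 (0.057), Iapp 0.48 (0.0586), Scg3 0.33 (0.0623), Cycs 0.61 (0.0851), Atp5g1 0.40 (0.116), Ivd -0.42 (0.0763), Insig1 0.48 (0.0565) and Idi1 0.39 (0.0994). Without knockout male 3 Npy had -1.12 (0.0832) and Dnajb1 0.86 (0.0812).

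In the beta-cell line (n = 4 against 4) 3 genes were higher and 14 lower in males, and islet hormones of non-beta cells were among them. Same-numbered knockout and control mice of a sex had the same age and were taken as pairs, so that each sex rests on 2 pairs, while the fit and the permutation took the 8 animals as independent. Without knockout male 1, low in Y-linked transcripts, 24 genes were called. Gcg fell by 1.33 (adjusted p = 0.0385), from 80390 ± 26390 CPM in females to 31640 ± 4843 CPM in males, Sst by 0.98 (0.0178), Irx2 by 0.94 (0.0377) and Slc38a5, an amino acid transporter of alpha cells, by 1.41 (0.0178; 58.3 ± 11.03 to 21.8 ± 2.33 CPM). The other genes that fell included Sgce (-1.25), Eef1a2 (-1.12), Gpx3 (-1.12), Klhl13 (-1.11), Higd1a (-1.10), Rbp4 (-1.07, 0.0318) and Oat (-0.99, 0.0341), and Fam135b rose by 1.01 (0.0409; 8.54 ± 0.522 to 17.2 ± 2.76 CPM). Of 15 alpha genes 4 fell over all genes and 11 when adjusted over the list alone (median -0.84; camera adjusted p = 1.91e-08, adjusted p = 0.106 with an estimated correlation; fry 0.00481). Of 12 delta and PP genes 2 fell, and 8 fell and 1 rose when adjusted over the list alone (median -0.83; camera adjusted p = 1.85e-07, adjusted p = 0.16 with an estimated correlation; fry 0.00972). The alpha score was lower in males (male minus female -0.70, exact permutation p = 0.0556, the smallest possible with 8 independent animals), and so was the delta and PP score (-0.73, 0.0556).

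Identity genes ranked higher in beta-cell line males (median 0.25, adjusted p = 0.001), with 5 higher and 2 lower members when adjusted over the list alone. Unfolded protein response (0.11, 0.0115), polyadenylation factor (0.11, 0.0444) and insulin secretion genes (0.05, 0.0492) also ranked higher, and disallowed (-0.42, 0.001), stellate, mesenchymal and Schwann cell (-0.79, 0.001), immediate early (-0.87, 0.00268) and oxidative phosphorylation genes (-0.08, 0.0115) lower; all of these camera calls had an adjusted p of 0.644 with an estimated correlation. Sex-linked (-0.44, 0.00176), immune (-0.32, 0.0115) and dedifferentiation genes (-0.28, 0.0343) ranked lower too (adjusted p = 0.226, 0.698 and 0.562 with an estimated correlation). Sdf2l1 had 0.43 (adjusted p = 0.231), Atf4 0.32 and Fev -0.99 (0.0549). In edgeR 2323 genes had an unadjusted p under 0.05; DESeq2 called 710 and limma-voom 14. The edgeR count was 0 without knockout female 1 or 2, control female 2, knockout male 2 or control male 1, 9 without control female 1 and 1 without control male 2. No gene kept its call in all 8 such fits. Slc38a5 then had log2 changes from -1.30 (adjusted p = 0.0659, without control female 2) to -1.45 (0.0566, without control male 1).

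Sex differences of the lines were compared across the same 16215 genes. Of the 14 genes lower in males of the beta-cell line 7 were also called lower in males of the whole-body line, against 0.33 for independent lists (Fisher's exact test, p = 1.2e-08), among them Gcg, Gpx3, Irx2, Mamld1, Sgce and Slc38a5. Of the 3 higher genes 0 were shared (expected 0.12; edgeR calls at the adjusted threshold). At an unadjusted p under 0.05, 713 genes were shared against 579.8 (odds ratio 1.4, 95% interval 1.27 to 1.55), 530 of them (74.3%) in the same direction. At an unadjusted p under 0.01, 161 genes were shared against 82.7 (2.34, 1.93 to 2.81), 148 of them (91.9%) in the same direction. The log2 fold changes correlated weakly across genes (Pearson r 0.238, Spearman rho 0.193), which are not independent replicates.

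**Figure D4:**
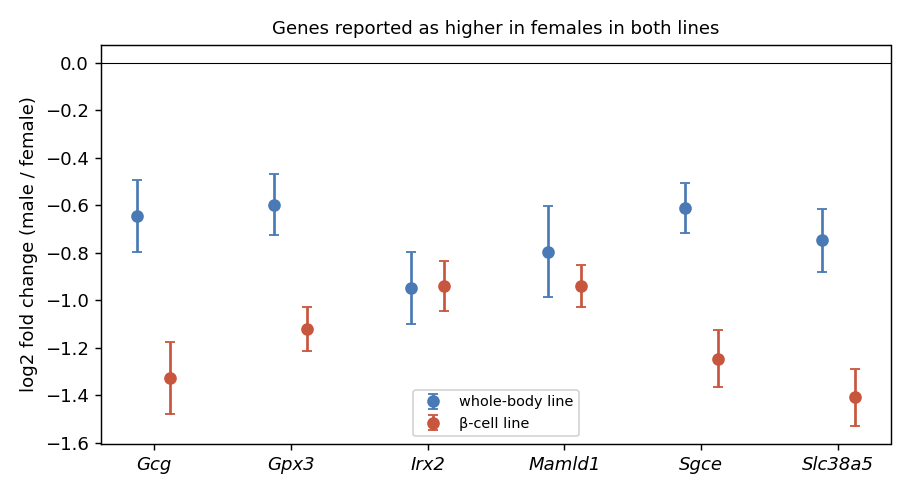
Male minus female log2 fold change, with SE as bars, of 6 of the 7 genes called lower in males of both lines, in the whole-body (blue) and beta-cell line (red). All 12 values lie below 0, which the choice of genes called lower in both lines fixed in advance.

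Autosomal genes called between the sexes of the beta-cell line were tested as sets in the whole-body knockout effect. The 9 genes higher in females had a camera p of 0.264 in knockout females and 0.0902 in knockout males, and the 3 higher in males 0.921 and 0.612, and neither set passed. The set higher in females gave a camera p of 0.000181 in males without knockout male 2 of the whole-body line, and 0.0292 without control male 2.

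Lists without a camera call in any comparison of knockout with control were those of the cell cycle, immediate early genes, polyadenylation factors, CPEB1 targets and Cpeb1 neighbours. Their medians in whole-body females were 0.15, 0.28, -0.08, 0.04 and -0.05.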

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

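The tests of explanations for chromosome 7, for Aldh1a3 and for alpha cell genes were chosen only after the results were seen, as were the windows around Cpeb1; the counts over other splits of the libraries were planned.

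Genes near Cpeb1 differed between knockout and control islets more often than other genes in both lines. Of the 6 genes called over both whole-body sexes 5 lie on chromosome 7. Only 2900076A07Rik and Sh3gl3 lie within 5 Mb of Cpeb1, while Me3, Aldh1a3 and Gm34225 lie farther away. In the beta-cell line 4 of the 6 genes called over both sexes lie on chromosome 7, Cpeb1 among them. An effect of the deletion on its immediate neighbours alone is argued against, since the excess in the beta-cell line reached genes 5 to 25 Mb away (odds ratio 5.12, 95% interval 3.34 to 7.63). That interval takes neighbouring genes as independent, and no splits were run for it. In the same line the interval under 1 Mb held 1 (3.97, 0.758 to 13.3), and that beyond 25 Mb lay above 1 (1.57, 1.14 to 2.13). The control female library rich in ribosomal RNA is argued against as well. Without it the odds ratio within 5 Mb in the whole-body line was 6.69 (3.98 to 11). Flanking DNA of another strain carried with the targeted allele is a candidate explanation, although no sequence variant could be read from counts. The interval for 5 to 25 Mb lay above 1 in the whole-body line over both sexes as well (1.85, 1.15 to 2.84) and in its males alone (1.69, 1.09 to 2.53). In whole-body females alone it held 1 (1.2, 0.791 to 1.76). Whether loss of CPEB1 also acted on other chromosomes stays open, because the genes shared by the lines off chromosome 7 exceeded independent lists at an unadjusted p under 0.05 (1.81, 1.32 to 2.46) but not detectably at 0.01 (1.95, 0.23 to 7.41), and 23 of 100 splits of the whole-body libraries gave as large a value, up to 2.81. For the excess within 5 Mb in the whole-body line 100 of the 200 possible splits were run. Only the real one reached 6.45 and the highest other gave 5.1, so that chance is argued against but not excluded. Without control female 3 of that line the odds ratio was 2.38.

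Aldh1a3 was raised in whole-body knockout males and not detectably in knockout females, and the male and female effects differed by 2.46 on the log2 scale (edgeR adjusted p = 5.95e-05 among the 6 called genes, 0.12 over all genes). A difference in age between the males is argued against, since Aldh1a3 had 2.69 with age as a covariate (edgeR adjusted p = 0.00706). Flanking DNA that acts alike in both sexes is argued against by the intervals. The upper 95% bound in females, 0.70, lay below the lower bound in males, 2.15. Flanking DNA carried by, or active in, the knockout males alone stays open, since these bounds cannot reach it. Aldh1a3 lies on chromosome 7. There, genes 5 to 25 Mb from Cpeb1 had an odds ratio of 1.69 (95% interval 1.09 to 2.53) in whole-body males and 1.2 (0.791 to 1.76) in females. The makeup of the preparations stays open: with the acinar score as a covariate the log2 fold change was 2.48 and its SE went from 0.235 to 0.301, so that the wider error ended the call (adjusted p = 0.0907). A hypothesis of beta cell dedifferentiation in these males also stays open, since 12 of the 16 other members of that list lay above 0 (median 0.48; fry p = 0.0117; two-sided exact permutation p = 0.1, the smallest possible with 3 against 3) while beta cell identity genes had a median of 0.01. The interval in beta-cell knockout males, -1.88 to 1.29, lies below the lower bound in whole-body males, but line and batch cannot be told apart.

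Alpha cell genes were lower in male than in female islets of both lines. A difference in age between the sexes is argued against in the whole-body line, since with age as a covariate the median of the list was -0.53. In the beta-cell line the median was -0.92, but females were 107 and 108 days old and males 111 and 80 days. The age term there rests on males numbered 1 against 2 and cannot be told apart from the pair or from knockout male 1, low in Y-linked transcripts. A larger share of beta cells that dilutes every other cell type alike stays open. Of 12 medians of other cell type lists over both lines, 11 lay below 0. In the whole-body and beta-cell line delta and PP genes had -0.39 and -0.83 and immune genes -0.2 and -0.32. Stellate, mesenchymal and Schwann cell genes had -0.19 and -0.79, and acinar genes -1.82 and 0.33. Endothelial genes had medians of -0.01 and -0.07 and duct genes -0.19 and -0.05 in the whole-body and beta-cell line, against -0.48 and -0.84 for alpha cell genes, but the alpha score minus the mean of the duct and endothelial scores differed between males and females by -0.27 in the whole-body line (exact permutation p = 0.32) and by -0.60 in the beta-cell line (exact permutation p = 0.0556, the smallest possible with 8 animals taken as independent). Fewer alpha cells in male islets and lower expression per cell both stay open: 12 of 12 values of 6 alpha cell genes lay below 0, which decides nothing, since all 6 were already called lower in whole-body males when they were chosen, and Gc, another member of the list, rose by 0.59 there (edgeR adjusted p = 0.00927). The design offers sex as the biological difference, and no count of cells was measured.

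Other results stood out because a knockout effect differed between the sexes. In the whole-body line these were Me3 (0.54), Gm34225 (0.86) and Sh3gl3 (-2.15), tested among the 6 called genes. The 6 genes were chosen by calls in the same libraries, and over all genes 0 passed. In the beta-cell line the genes were Trim12a (9.68, fitted against libraries at 0) and Capza1-ps1 (-3.24), tested among the 6 genes called in that line and chosen the same way. Over all genes neither passed (edgeR adjusted p = 0.179 and 0.115). Gene lists whose whole-body effect differed between sexes were, as camera adjusted p, immune (6.94e-09, median difference -0.92), interferon (9.86e-05, -0.48), stellate, mesenchymal and Schwann cell (9.86e-05, -0.73), disallowed (0.000792, -0.39), endothelial (0.00949, -0.30), prolactin response (0.0102, 0.34), acinar (0.0187, -0.93) and insulin secretion genes (0.0419, 0.21), all with an adjusted p between 0.811 and 0.925 with an estimated correlation. Beta-cell knockout effects differed for acinar (1.06e-06, -0.55), interferon (5.4e-06, 0.43), immune (1.95e-05, 0.84), delta and PP (0.00011, 0.53), disallowed (0.0131, 0.44), identity (0.0147, -0.14), endothelial (0.0147, 0.34), polyadenylation (0.0262, -0.11) and stellate, mesenchymal and Schwann cell genes (0.038, 0.64), with an adjusted p between 0.781 and 0.789 with an estimated correlation. The whole-body acinar difference turned without control female 3 (camera adjusted p = 0.66). Those of the beta-cell line turned for acinar genes without knockout male 2 (0.000306), for endothelial genes without control male 2 (0.683), and for stellate genes without control male 2 (0.683) or control female 1 (0.526).

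Between the lines the knockout effect differed for Gm34225 (2.42), and for Trim12a (fitted 5.94) and Rps13-ps2 (fitted 7.03), both fitted against beta-cell knockout females at 0. The lists were acinar (camera adjusted p = 2.97e-15, median difference -3.35), endothelial (4.67e-09, 0.54), oxidative phosphorylation (1.64e-07, 0.17), identity (0.00735, -0.14), unfolded protein response (0.0203, 0.12), duct (0.0437, 0.27) and prolactin response genes (0.0437, -0.18), with an adjusted p between 0.606 and 0.697 with an estimated correlation. Dedifferentiation genes (0.000119, 0.37) also differed with an estimated correlation (adjusted p = 0.0412).

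Other splits of the same libraries were counted for each result. For the 6 genes of the whole-body mean and the 1037 genes between whole-body sexes 100 of 200 possible splits each were run. Only the real split reached these counts (highest others 1 and 10), so that chance is argued against but not excluded. Chance stays open for the shared sex differences (39 of 100 splits gave at least 1.4, up to 3.07). It also stays open for the 3 genes that differ between lines (17 of 50 splits, highest other 81, which points to a structure of the samples). The male minus female whole-body effect called 0 genes in edgeR (highest other 1; 2000 genes at an unadjusted p under 0.05, DESeq2 472, limma-voom 0), a count that any split reaches (100 of 100), so that its splits tell nothing. The 10 splits within a whole-body sex are too few for a share under 0.05 (females 1 gene, highest other 0; males 4, highest other 1). So are the 18 splits of the beta-cell libraries: the mean effect called 6 genes and the highest other split 210, the male minus female effect 0 (edgeR; 212 genes at an unadjusted p under 0.05, DESeq2 7, limma-voom 0) and 210, and the sexes 17 and 1. In 7 of these 18 splits the mean effect called at least 6 genes. The split with 210 genes in the mean effect sets females numbered 2 and males numbered 1 against the rest. The one with 210 in the male minus female effect sets animals numbered 1 against those numbered 2. These are the same contrast of the same libraries, so that the 2 counts of 210 are 1 result. It parts 0 of the 4 pairs of same-numbered animals, which points to a structure of the samples. Males numbered 1 and 2 also differed in age (111 and 80 days), and knockout male 1 is the library low in Y-linked transcripts. Among the 8 splits that part all 4 pairs the highest other called 1 gene, and among the 10 that part fewer the highest called 210.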

How the results depend on the processing

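The alternatives were planned, apart from the removal of Rn18s and Lars2, the windows around Cpeb1 and the overlap without chromosome 7, which were chosen after seeing the data. Alternatives for TPM or FPKM were not applicable to counts. The knockout effect on Cpeb1 stayed below 0 in every fit within a line, without Rn18s and Lars2 all 26 comparison results were kept, and 2900076A07Rik kept its call over both whole-body sexes in 21 of 22. Counts of calls depended on the tool, on single libraries and, between the sexes, on the use of control libraries alone, which also leaves 3 against 3 whole-body animals. The lists depended on the correlation assumed: of 90 list calls with the preset correlation 1 was left with an estimated one. DESeq2 gives no list results here, the block cannot give contrasts between sexes, and fits that leave 1 library in a beta-cell group assume that it varies like the other groups. At this depth genes near 0 in a group have wide errors, and in the simulation edgeR recovered 4% of 2-fold and 78% of 4-fold changes in whole-body females (18282 genes). The cause of the differences given here was not tested, except that fewer libraries or a looser threshold change a count by construction.

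With DESeq2 the whole-body calls were 121 in females, 293 in males, 197 over both sexes, 472 for males minus females and 2660 between the sexes, and the beta-cell calls were 29, 19, 38, 7 and 710; the lines differed for 14 genes. DESeq2 also called Cpeb1 in whole-body females (-0.92), males (-0.94) and both (-0.93), and in beta-cell females (-1.03) and males (-1.12). In the simulated means of both sexes DESeq2 called 28 unchanged genes in the whole-body and 27 in the beta-cell line, against 9 and 7 with edgeR. Limma-voom called 0, 7 and 10 genes in whole-body females, males and both, 7 between lines, and Cpeb1 over both whole-body sexes (-0.96); the set higher in females had a camera p of 0.00812 in whole-body males. With no filter Cpeb1 was called over both whole-body sexes (-0.91). DESeq2 size factors in edgeR, the stricter filter and age as a covariate each left 1 call in beta-cell females. At an adjusted p of 0.1 the sexes differed for 2048 whole-body and 30 beta-cell genes and the lines for 5. With age 616 genes, and in controls alone 11 whole-body and 1 beta-cell genes, differed between sexes. With only the groups compared the calls were 0 and 8 in whole-body and 0 and 1 in beta-cell females and males.

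Same-numbered whole-body animals did not pair: their correlations were 0.17, -0.21 and 0.14 in females and -0.23, 0.03 and -0.16 in males, and not every animal correlated best with its own number. The replicate block called 0 genes in whole-body females, males and both (limma-voom 0, 7 and 10; DESeq2 121, 293 and 197) and 1 for males minus females. A call lost under this block is therefore no sign of a weaker effect. In the beta-cell line, where same-numbered animals of a sex had the same age, edgeR with the block called 3 genes in females, 0 in males and 8 over both, among them Cpeb1 (adjusted p = 0.018), and 7 more list calls were made with camera.

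With the acinar score as a covariate edgeR called 0 genes in whole-body females and males, 1 over both and 2049 between sexes, and the set higher in females had a camera p of 0.0421 in whole-body males. Lists that turned direction, as camera adjusted p, were acinar in females (0.569); polyadenylation (0.0198), duct (0.0298), endothelial (8.29e-08) and oxidative phosphorylation genes (0.0687) in males; disallowed (0.000382), identity (0.314), polyadenylation (0.0273), duct (0.00183), endothelial (0.000382), interferon (0.0135), oxidative phosphorylation (0.322), prolactin (0.918) and stellate genes (9.2e-06) over both; and endothelial genes between sexes (0.0108). With age the acinar and endothelial lists turned between beta-cell sexes (0.0089 each), and in controls alone immune genes in the whole-body (0.00376) and acinar genes in the beta-cell line (2.47e-15) turned. In sets of the 100 smallest p, the genes higher in males turned in whole-body females (a camera p of 4.24e-08, and 0.219 with an estimated correlation) and males (0.00488 and 0.513). A camera p compares genes with genes, and no exact test over animals was run for these sets.

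Leaving out 1 library gave, as lowest and highest, 0 (without knockout female 2) and 32 calls (without control female 3) in whole-body females, 2 (knockout male 3) and 5 (control female 3) in males, 2 (knockout female 2) and 11 (control female 3) over both, 0 (knockout female 1) and 3 (knockout male 2) for males minus females, and 308 (control male 1) and 1656 (control female 3) between sexes. Beta-cell calls were 0 (knockout female 1) and 2 (control female 2) in females, 0 (knockout female 1) and 3 (control female 1) in males, 0 (knockout female 1) and 4 (control female 1) over both, 0 (knockout female 2) and 1 (knockout female 1) for males minus females, and 0 (knockout female 1) and 24 (knockout male 1) between sexes. Cpeb1 lay between -1.06 (control female 3) and -0.79 (control female 1) in whole-body females, -1.01 and -0.87 (the same libraries) over both, and -1.145 (control female 1) and -0.99 (control female 2) in the beta-cell line over both. The overlap of knockout effects had odds ratios of 1.07 (whole-body control female 3) to 3.64 (beta-cell knockout male 1), and the set higher in females a camera p of 0.000181 (knockout male 2) to 0.832 (knockout male 3) in whole-body males.

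Lists that turned without some library had these lowest and highest camera adjusted p, each with the library left out. In whole-body females oxidative phosphorylation genes had 4e-08 (control female 3) and 0.0828 (control female 1), and stellate genes 0.000173 (control female 3) and 0.723 (control female 2). Over both sexes stellate genes had 0.00703 (control female 2) and 0.955 (knockout male 3). For males minus females acinar genes had 1.7e-06 (control female 2) and 0.749 (knockout female 1), and oxidative phosphorylation genes 0.000209 (control female 3) and 0.928 (control male 1). In beta-cell females immune genes had 6.2e-06 (knockout female 1) and 0.937 (knockout female 2), and stellate genes 0.000871 (control female 2) and 0.795 (knockout female 2). In beta-cell males the lowest came without knockout male 2 and the highest without control male 2 for cell cycle (4.16e-11, 0.777), interferon (4.51e-09, 0.246) and immune genes (2.6e-07, 0.865). There immediate early genes had 4.7e-07 (knockout male 2) and 0.456 (knockout female 2), identity genes 0.00885 (knockout male 2) and 0.859 (control female 2), acinar genes 9.39e-71 (knockout male 1) and 0.0275 (control male 2), and endothelial genes 2.28e-08 (control male 2) and 0.318 (knockout female 1). Acinar genes had 4.82e-33 (knockout male 1) and 0.867 (control female 1) over both beta-cell sexes, and 2.67e-19 (knockout male 2) and 0.966 (control female 1) between them. Beta-cell males minus females gave acinar 8.35e-77 (knockout male 1) and 0.00623 (knockout female 2), cell cycle 6.91e-06 (knockout male 1) and 0.634 (knockout female 1), immediate early 1e-04 (knockout male 2) and 0.92 (knockout female 1), endothelial 2.49e-08 (control male 1) and 0.836 (knockout male 1), and stellate genes 3.54e-07 (control male 1) and 0.683 (control male 2). Between lines stellate genes had 0.0415 (beta-cell control male 1) and 0.981 (beta-cell knockout female 2), and immediate early genes 0.000799 (beta-cell knockout male 1) and 0.942 (whole-body control male 1).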

Other observations

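The tests of genes listed in only 1 beta-cell table were chosen after the data were seen, and so were the genes named in this part.

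None of the 3 lymphocyte genes given here passed between genotypes in edgeR with all libraries. Blk, a kinase of the B-cell receptor, had a mean of 2.62 CPM in knockout and 0.685 CPM in control females of the whole-body line, and 0.0728 CPM in knockout and 2.00 CPM in control males. In the beta-cell line Igha, the IgA heavy chain of plasma cells, had 9.04 CPM in knockout and 30.0 CPM in control females, and 21.9 and 4.38 CPM in males. Jchain, which joins antibody chains, had a male minus female difference of the knockout effect of 4.05 (edgeR adjusted p = 0.479).

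Xist, the RNA that coats the inactive X chromosome, had 208.3 CPM in control female 1 of the whole-body line, against 9.9 to 16.7 CPM in the other whole-body females. In that library Rn18s took 60.5% of the counts and Lars2 10.3%, against at most 7.49% and 1.38% in the other whole-body libraries. The insulin genes took 5.32% of its counts, and between 20.9% and 28.7% in the others.

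Genes listed in only 1 beta-cell table were tested within that sex where they passed the filter on low counts. Of the 298 such genes of the female table, 0 were called in edgeR and 20 had an unadjusted p under 0.05, among them Apol7c (5.82, adjusted p = 0.648), an apolipoprotein L gene, and the regulatory T-cell gene Foxp3 (2.07, 0.999). Of the 419 of the male table, 0 were called in edgeR and 20 had an unadjusted p under 0.05, among them Aqp5, a water channel (-2.66, adjusted p = 1), and Hp, haptoglobin (4.41, 1). These genes were not run with other tools.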
